A study of Mus musculus with 12 samples.

How the data were processed

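Epididymal fat of male mice, C57BL/6 in the sample labels and C57BL/6N in the growth protocol, was profiled with 1 Affymetrix whole-transcript array per sample, 12 arrays in all, 3 for each of 4 diets. The labels name a control diet (CD) and 3 caloric restriction diets that gave 85%, 70% and 55% of the control diet's calories (CR85, CR70 and CR55), and number the samples of a diet as biological replicates. Per the labels' protocols, total RNA was extracted with Trizol and 100 ng of it was turned into biotinylated single-stranded cDNA by the Affymetrix sense target protocol. The deposited table holds log2 values per probe set, as the range from 1.15 to 14.4 shows, and Partek 6.6 is the tool named in the submitters' processing notes. The method that summarized and normalized the probe sets is not given in the sources used here. The deposited values had been normalized between arrays by the authors, because the 12 columns share a median of 6.12 and quartiles of 4.68 and 7.68. A shift of all transcripts of a sample would have been removed by that step. A detection call or a background level per probe was not used here, so the precision of a value is known only from the 3 arrays per diet, and the size of a change is uncertain where a group has a low value.

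Gene names came from the platform annotation that accompanies the deposited table. Of 28853 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 5443 had no listed gene. The last 2 kinds were left out of the tests, and no gene was named from them. Entrez identifiers of 21698 of the probe sets with 1 symbol were found in a RefSeq gene table (GRCm38.p6), which changed 0 symbols. No genomic coordinates are printed, because the build behind the annotation is not given in the sources used here. Where a gene had several probe sets, as 999 genes did, the probe set with the highest mean over all 12 arrays stood for it, which left 19938 genes.

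The 12 arrays entered a single fit of 4 group means with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Fold changes are differences of group means on the log2 scale, and the value after ± is the standard error of the fit, with 3 arrays in each group. The p-values were two-sided, were adjusted by the Benjamini-Hochberg method over all genes of a comparison and were called at an adjusted p under 0.05. Each restricted diet was compared with the control diet, and the restricted diets with each other. A slope over the percentage of restriction, per step of 15%, was tested in a linear fit, and moderated F tests asked for a departure from that line and for any difference among the 4 diets. The 31 gene lists (metabolic pathways, adipocyte functions, other cell types and neighbouring tissues) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. Where no test is named, a list called or not called refers to camera at the preset correlation. Counts given over the list alone used p-values adjusted within that list and comparison only, with no correction across the 31 lists. List names were matched by symbol and then by synonym. In 2 cases the synonym led to another gene, Pigq for Gpi1 in glycolysis and Loxl3 for Loxl2 in the matrix list, and values without these members are given beside the lists. Python 3.11.15 drew the figures.

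The groups, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each restricted diet against the control diet, the 10 genes with the largest rise and the 10 with the largest fall among those called whose 3 restricted arrays all lay beyond the 3 control arrays. Where nothing was called, it took the 3 genes with the smallest p in each direction. From each list it took up to 4 members with the smallest p in CR55 against CD, and the called members where these were 6 or fewer. It always took Lep, Adipoq, Mest, Sfrp5, Ucp1, Fasn, Acly and Pck1, and from each comparison of restricted diets up to 5 genes in each direction. Predicted genes, olfactory and vomeronasal receptors, small RNA genes and antigen receptor segments were counted and not named. Genes outside the rule are marked as chosen after their values were seen.

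The alternatives were another normalization of the deposited values, a filter that left out the 33.3% of genes with the lowest mean, the mean of a gene's probe sets, every probe set tested, other variance models, array weights, the replicate number as a block, only the 6 arrays compared, other thresholds and each array left out in turn. Fits without 4 arrays and with a list mean as covariate, and lists without the 2 members matched to another gene, were added after the data had been seen.

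The gene and list tests were tested on simulated data built from the control means and residual spread of the 19938 genes. In 3 simulations of CR55 against CD, with 150 genes planted per size of change, 6.67% of planted changes of 0.50 on the log2 scale, 62.7% of changes of 1, 92.7% of changes of 2 and 98.7% of changes of 3 were recovered, and 5.33% of the calls were false. Of 2 planted lists, camera called 2 at the preset correlation, along with 0 of the 29 others, and 2 with an estimated correlation. The simulated genes varied independently of each other, so these list results do not show how camera behaves on correlated genes. In the real data, mixed splits of the CR55 and CD arrays called 2 to 19 lists at the preset correlation.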

Results

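The data describe gene expression in epididymal fat, a visceral depot beside the testis and epididymis, after short-term caloric restriction of graded strength. Per the labels, male mice ate a control diet of 17.11 kcal per day or diets of 14.51, 11.91 or 9.32 kcal per day for 10 weeks. They were 18 weeks old at sampling. The control diet was itself set at 95% of ad libitum intake, so restriction is counted from that diet and not from free feeding. The restricted diets, labelled CR85, CR70 and CR55, amount to 15%, 30% and 45% restriction and differed from the control diet in cornstarch, dextrose and sucrose. Each diet was represented by 3 arrays, numbered as biological replicates in the labels, which limits the precision of every value given here. Arrays correlated with the others of their group at a mean r of 0.987 to 0.989 in CD, 0.968 to 0.977 in CR85, 0.978 to 0.985 in CR70 and 0.968 to 0.978 in CR55, across probe sets, which are not independent replicates. All groups carry the names in the labels.

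Transcripts of testis germ cells stood out in 4 of the 12 arrays. The mean over the preset testis list was 7.61 in CR85 replicate 2, 6.91 in CR70 replicate 1, 8.29 in CR70 replicate 3 and 8.97 in CR55 replicate 2, against 5.12 to 5.46 in the control arrays. Gapdhs, a glycolytic enzyme of sperm, averaged 8.10 in those 4 arrays and 5.38 in the other 8. A list of epididymis genes lay between 4.50 and 4.72 in all 12 arrays. The 4 arrays belong to all 3 restricted diets and to no control, so that counts of genes without them are given beside the comparisons.

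**Figure D1:**
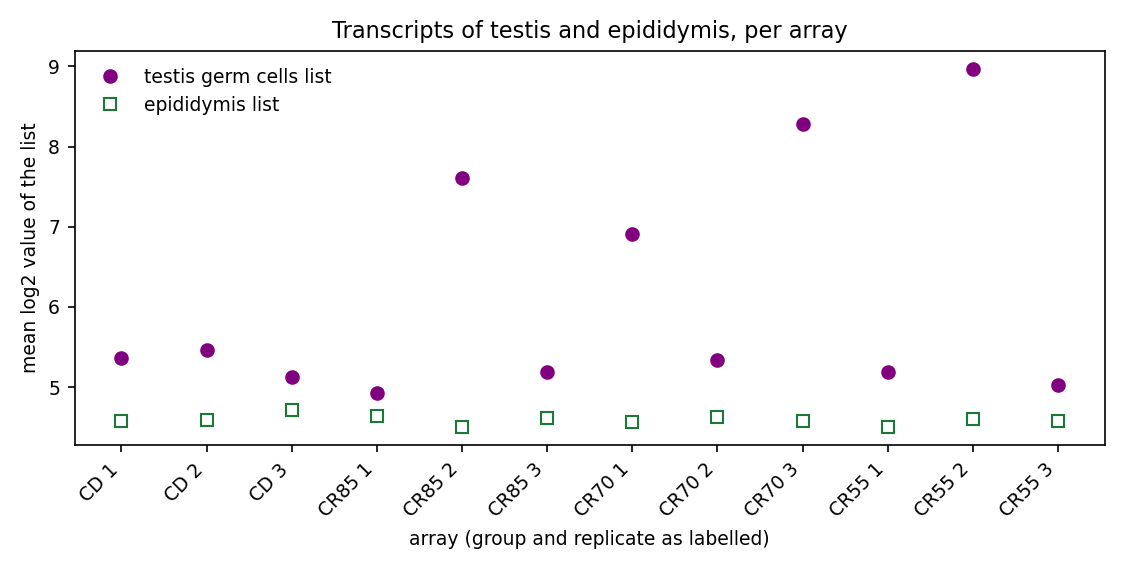
Mean log2 value of the 12 testis germ cell genes (filled circles) and the 15 measured epididymis genes (open squares) on each of the 12 arrays. The testis mean reaches 6.91 to 8.97 on 4 arrays of restricted mice and is at most 5.46 on the other 8.

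The comparison of CR85 with CD asks what the restriction labelled as mildest changed, and it gave the largest response of the 3 diets. Genes known to follow the expansion of fat mass were among those that fell most: Mest, an imprinted gene (probe set 10537062), by -5.64 ± 0.49 on the log2 scale, Nnat by -5.38 ± 0.52 and Sfrp5, a secreted Wnt inhibitor, by -3.39 ± 0.49. Lep, the gene of the hormone leptin, fell 11.2-fold (-3.48 ± 0.46) and Npr3, the clearance receptor of natriuretic peptides, 7.90-fold (-2.98 ± 0.29). Among the genes that rose most were Acsm3, a medium-chain acyl-CoA synthetase (9.92-fold, 3.31 ± 0.55), the fatty acid elongase Elovl3 (9.34-fold, 3.22 ± 0.59), the fructose transporter Slc2a5 (7.48-fold) and Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase (5.15-fold). Macrophage and matrix genes fell together with the markers of fat expansion.

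With limma and Benjamini-Hochberg adjustment, 1810 of 19938 genes were called in CR85 against CD, 657 higher and 1153 lower, and 155 and 403 of them changed at least 2-fold. Sncg (γ-synuclein) fell by -4.47 ± 0.32, Mageb18 by -3.78 ± 0.40, the transporters Slc6a13 and Slc5a7 by -3.24 ± 0.50 and -3.13 ± 0.22, and Mmp12, the macrophage elastase, by -2.95 ± 0.49. Tlcd4 rose by 3.21 ± 0.57, Mpzl2 by 3.20 ± 0.36, Lrtm1 by 2.80 ± 0.39, Tst by 2.74 ± 0.28, Cyp2f2 by 2.48 ± 0.31 and Cyp51, an enzyme of cholesterol synthesis, by 2.33 ± 0.42. The adjusted p of these 20 genes ranged from 0.000126 (Sncg) to 0.0145 (Slc2a5). Groups did not overlap in 27.8% of genes, against 10% by chance. The count was 831 without CD replicate 1 and 1187 without CR85 replicate 1, and 1701 without the 4 arrays with testis transcripts. With only the 6 arrays compared it was 1130, and with array weights 2903.

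**Figure D2:**
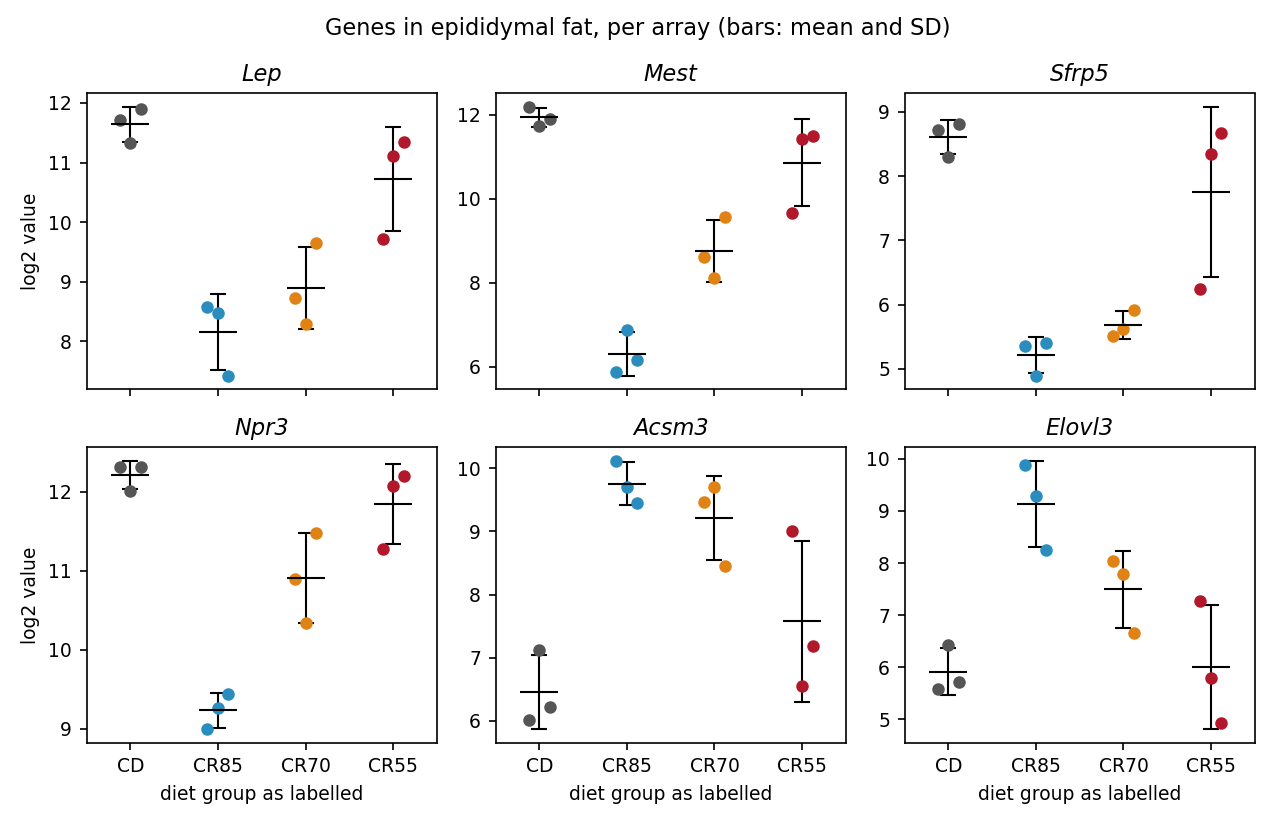
Log2 values of 6 genes on each array, by diet group as labelled, with points for arrays, horizontal bars for the mean and whiskers for the SD of 3 arrays. Lep lies at 11.3 to 11.9 in the control arrays, 7.42 to 8.58 in CR85 and 9.72 to 11.3 in CR55.

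Energy metabolism genes rose in CR85. Of 19 measured genes of de novo lipogenesis, 11 rose and 0 fell (16 and 0 when adjusted over the list alone), with a median log2 change of 1.11. Acacb rose by 2.13 ± 0.29, Aacs by 1.69 ± 0.25, the transcription factors Mlxipl and Srebf1 by 1.60 ± 0.28 and 0.97 ± 0.15, Acly, which makes cytosolic acetyl-CoA, by 1.36 ± 0.33 and Tkt by 1.11 ± 0.24. Fasn, at rank 9 to 25 of all probe sets by value, differed by 0.45 ± 0.13 (adjusted p = 0.0507). In the tricarboxylic acid cycle, 15 of 22 rose and 0 fell (18 and 0 over the list alone), among them Pdha1 (1.19 ± 0.19), Sdha (0.94 ± 0.14), Idh3g and Dlst. Of 68 genes of oxidative phosphorylation, 28 rose and 0 fell (52 and 1 over the list alone), with Ndufa10 at 0.90 ± 0.14, Ndufv1 at 0.78 ± 0.13, Ndufs7 at 0.70 ± 0.13 and Uqcrc1 at 0.64 ± 0.14. Fatty acid beta oxidation had 8 of 21 members up and 1 down (14 and 1 over the list alone). Acot2 (1.1 ± 0.19), Echs1 and Acaa2 rose, while Cpt1a, the entry step of fatty acids into mitochondria, fell by -0.90, a gene chosen after its values were seen. Glycolysis had 9 of 17 up and 2 down (9 and 2 over the list alone), with the glucose transporter Slc2a4 at 1.09 ± 0.21, Ldhb, Hk2 and Pfkm higher and Pfkp lower (-0.94 ± 0.16). Camera called these lists at adjusted p values of 2.83e-10, 6.24e-14, 2.30e-20, 1.05e-08 and 0.00114 in the order given. With an estimated correlation the adjusted p values were 0.193, 0.178, 0.178, 0.178 and 0.210. In the glycolysis list the name Gpi1 had been matched as a synonym to Pigq, which is not a glycolysis gene. Without it 9 of 16 rose and 2 fell (9 and 2 over the list alone), at adjusted p = 0.00196 and adjusted p = 0.217 with an estimated correlation.

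Cholesterol synthesis rose as a list (adjusted p = 8.19e-05 in camera, adjusted p = 0.324 with an estimated correlation), with 4 of 20 up and 1 down (6 and 1 when adjusted over the list alone). Cyp51, Fdft1 (1.72 ± 0.18), Sqle (1.05 ± 0.25) and Tm7sf2 rose, whereas Hmgcs1, an early enzyme of the pathway, fell by -1.04 ± 0.19. Circadian clock genes moved both ways, with 8 of 17 up and 2 down (10 and 3 over the list alone). Camera called the list as higher (adjusted p = 0.000258, adjusted p = 0.178 with an estimated correlation). Ciart rose by 2.29 ± 0.35, Dbp by 1.16 ± 0.23, Nr1d2 by 1.09 ± 0.14 and Per3 by 0.93 ± 0.16. The activators Arntl (-1.62) and Clock (-0.57), each chosen after its values were seen, fell. The time of day at sampling was not used here, and whether the diets differed in the timing of the clock was not tested. Glucocorticoid-responsive genes (adjusted p = 0.0239, adjusted p = 0.210 with an estimated correlation) had 6 of 17 up and 1 down, in the whole set and over the list alone, with Fkbp5 at 1.62 ± 0.14, Hsd11b1, which regenerates active glucocorticoid, at 1.00 ± 0.19, Klf9 and Mt1 higher and Angptl4 at -1.63 ± 0.31. That list was not called without CD replicate 3 (adjusted p = 0.0556) or CR85 replicate 2 (adjusted p = 0.101). The list of oxidative stress and NRF2 (adjusted p = 0.000258, adjusted p = 0.178 with an estimated correlation) had 4 of 22 up and 1 down (10 and 2 over the list alone). Gsta4 and Gpx3 rose by 1.37 ± 0.16 and 1.37 ± 0.15, Gsta3 and Srxn1 by 1.05 and 0.89, and the extracellular Sod3 fell by -1.04 ± 0.19.

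Genes of immune cells and matrix fell in CR85. Of 29 measured macrophage and inflammation genes, 21 fell and 0 rose (23 and 0 when adjusted over the list alone), with a median of -1.15, as for Mmp12, Ccl6 (-1.90 ± 0.23), Ctss (-1.37 ± 0.27) and Gpnmb (-1.13 ± 0.30). Of 31 matrix genes, 21 fell and 0 rose (25 and 0 over the list alone): Col5a2 by -1.53 ± 0.14, Postn by -1.52 ± 0.17, Col6a1 by -1.42 ± 0.26 and Col5a1 by -0.92 ± 0.15. Camera gave adjusted p values of 6.05e-16 and 9.54e-21, and adjusted p = 0.178 with an estimated correlation for both. The matrix list held Loxl3, matched as a synonym to the name Loxl2, and without it 21 of 30 fell (25 over the list alone), at adjusted p = 1.90e-21. B lymphocyte genes had 4 of 14 down (7 over the list alone), among them Cd79a, Ms4a1, Bank1 and H2-Ob, and T and NK lymphocyte genes 2 of 19 (6 over the list alone), Gzma (-1.76 ± 0.34) and Thy1 (-1.03 ± 0.16). These lists had adjusted p values of 0.000147 and 0.000411, and adjusted p values of 0.217 and 0.276 with an estimated correlation. The interferon list (median -0.41, adjusted p = 0.00117, adjusted p = 0.324 with an estimated correlation) had no member among its 18 that passed over all genes or adjusted over the list alone. Cell cycle genes had 4 of 21 down (5 over the list alone), Top2a (-1.67 ± 0.34), Ccna2, Mki67 and Cdk1, at adjusted p = 0.00103 and adjusted p = 0.247 with an estimated correlation. Among genes of the unfolded protein response, Pdia3, Edem1 (-0.92 ± 0.12) and Sdf2l1 made 3 of 21 down (3 over the list alone), at adjusted p = 0.00628, adjusted p = 0.210 with an estimated correlation and adjusted p = 0.0533 without CR85 replicate 3.

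Adipocyte genes moved both ways in CR85. The list of markers of fat mass expansion had 6 of 9 down and 0 up (6 and 1 when adjusted over the list alone), with Bmp3 at -2.48 ± 0.25, at adjusted p = 1.06e-05 and adjusted p = 0.178 with an estimated correlation. Of 14 adipocyte identity genes, Aoc3 (-1.03 ± 0.17), Lpl (-0.59 ± 0.11), the fatty acid transporter Cd36 (-0.56 ± 0.10) and Acvr1c fell and Slc2a4 rose (8 and 2 over the list alone), at adjusted p = 0.00964, adjusted p = 0.247 with an estimated correlation and adjusted p = 0.0867 without CR85 replicate 2. Adipose progenitor genes had 4 of 15 down and F3 up (5 and 2 over the list alone), with Sema3c at -1.55 ± 0.18, Cd55, Anxa3 and Gsn lower, at adjusted p = 0.0280, adjusted p = 0.276 with an estimated correlation and adjusted p = 0.134 without CR85 replicate 1. Endothelial genes had Cldn5 (-1.17 ± 0.25) as 1 of 17 down (1 over the list alone), at adjusted p = 0.00758, adjusted p = 0.447 with an estimated correlation and adjusted p = 0.101 without CR85 replicate 2. Among adipokines, Rarres2 (chemerin, -2.58 ± 0.29), Lep, Angptl4 and Rbp4 fell and Agt (1.02 ± 0.17) and Nampt rose, 4 and 2 of 11 (6 and 2 over the list alone). Camera at the preset correlation did not call the list (adjusted p = 0.10). Adiponectin (Adipoq) differed by -0.32 ± 0.11 (adjusted p = 0.106). Fatty acid uptake and triglyceride synthesis had 3 of 16 up and 4 down (6 and 6 over the list alone). Gpam (1.81 ± 0.22), Slc27a1 (1.58 ± 0.18) and Dgat1 (0.67, chosen after its values were seen) rose. Mogat2 (-2.04 ± 0.20), Pck1 (-1.66 ± 0.38), Lpl and Cd36 fell, and the list was not called (adjusted p = 0.597).

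Camera at the preset correlation did not call the remaining lists in CR85. Of 15 thermogenic adipocyte genes, Elovl3, Cidea (2.16 ± 0.34), the coactivator Ppargc1a (1.65 ± 0.26) and Cox8b (1.51 ± 0.21) rose and Otop1 fell (4 and 1 over the list alone; list adjusted p = 0.161). Ucp1, the uncoupling protein of brown fat, differed by -0.29 ± 0.14 (adjusted p = 0.237). Insulin and IGF signalling had Pik3r1 (1.08 ± 0.20) and Igf1r up and Grb14 (-1.39 ± 0.36), Igfbp5 and Irs2 down, 2 and 3 of 22 (3 and 3 over the list alone; list adjusted p = 0.775, with a median of 0.03 and a mean of -0.03). Lipolysis and lipid droplet genes had Plin4 (-1.02 ± 0.24) as 1 of 14 down (4 down and 3 up over the list alone; list adjusted p = 0.302). Acta1 (-2.35 ± 0.43) and Casq1 fell among 15 skeletal muscle genes (2 over the list alone; list adjusted p = 0.153) and Msln among 15 mesothelial genes (0 over the list alone; list adjusted p = 0.161). The muscle list was called without CD replicate 1 (adjusted p = 0.0122) and the mesothelial list without CD replicate 3 (adjusted p = 0.00706). Limma called 0 of 12 testis, 0 of 15 epididymis, 0 of 5 red blood cell and 0 of 30 ribosomal protein genes over all genes and over each list alone, and the lists had adjusted p values of 0.410, 0.627, 0.698 and 0.903. In all, camera called 20 of 31 lists, 9 up and 11 down, fry called 20 and camera with an estimated correlation called 0, with 8 at an unadjusted p under 0.05.

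**Figure D3:**
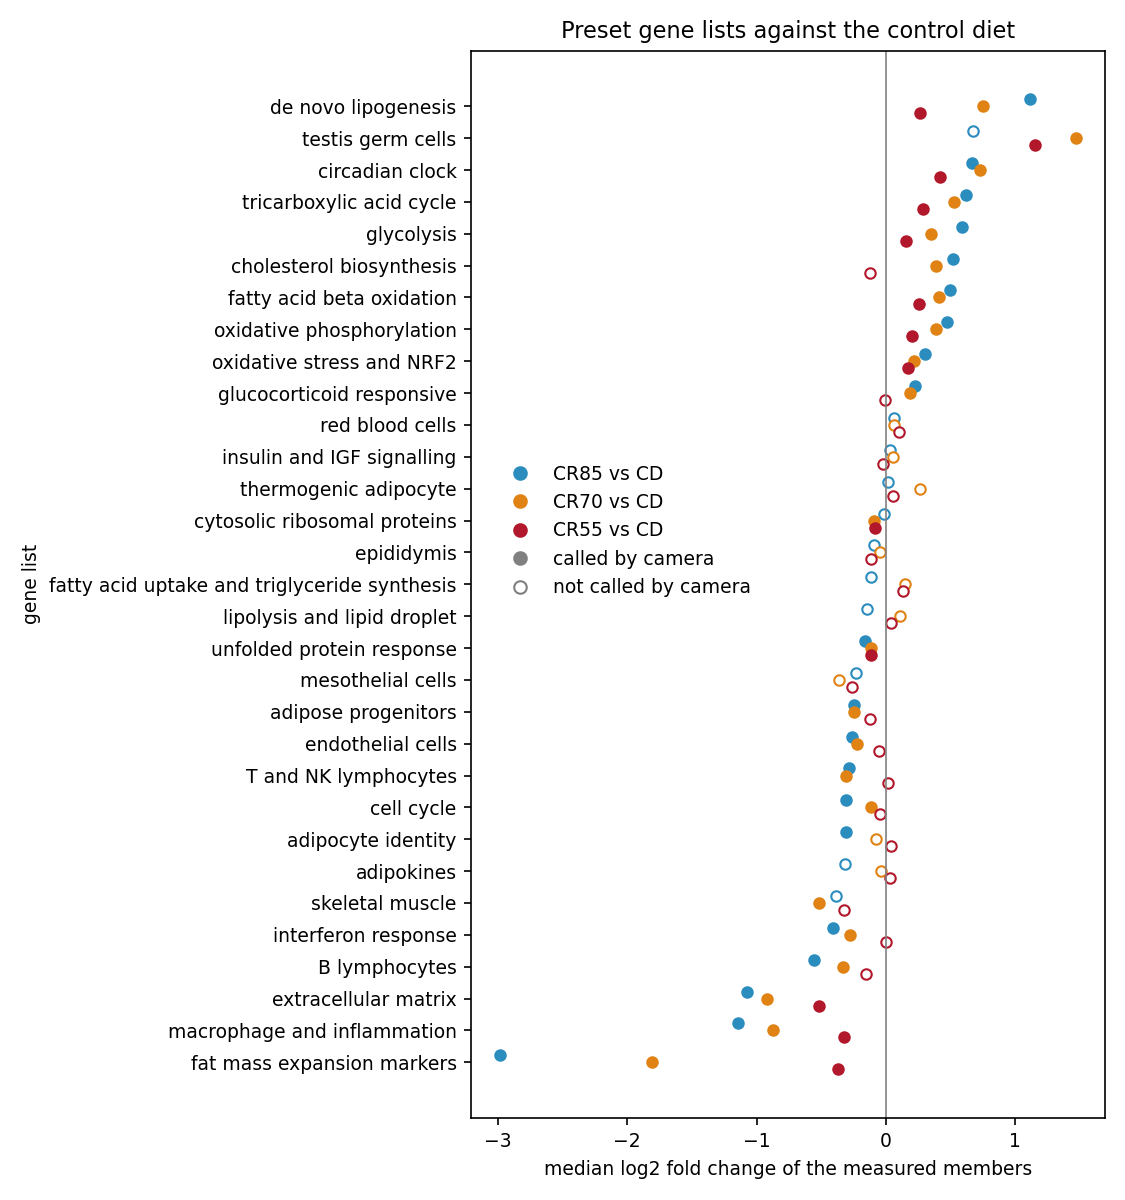
Median log2 fold change of the measured members of each of the 31 gene lists against the control diet, with colours for CR85, CR70 and CR55 and filled circles for lists called by camera at the preset correlation. The markers of fat mass expansion have medians of -2.98, -1.81 and -0.37 in CR85, CR70 and CR55.

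In CR70, the intermediate restriction, most of the called genes were also called in CR85. Mest fell by -3.18 ± 0.49 (9.04-fold), Sfrp5 by -2.92 ± 0.49, Lep by -2.75 ± 0.46 (6.75-fold) and Mageb18 by -3.31 ± 0.40. Tlcd4 rose 8.55-fold (3.10 ± 0.57), Acsm3 6.77-fold (2.76 ± 0.55), the clock gene Ciart 4.53-fold (2.18 ± 0.35), Gpd2 4.16-fold (2.06 ± 0.33) and Acacb, an acetyl-CoA carboxylase, 3.61-fold (1.85 ± 0.29). Further genes with the largest rises were Mpzl2 (2.24 ± 0.36), Rassf6 (2.08 ± 0.29), Fam13a (1.91 ± 0.30), Cidea (1.83 ± 0.34) and Oscp1 (1.81 ± 0.18). Further falls were those of Lipf (-2.86 ± 0.40), the eosinophil ribonuclease gene Rnase2a (-2.82 ± 0.34), Slc5a7 (-2.75 ± 0.22), Mmp12 (-2.65 ± 0.49), Emp1 (-2.29 ± 0.44) and Prr32 (-2.17 ± 0.30). The adjusted p of these 20 genes ran from 0.00152 (Slc5a7) to 0.0320 (Acsm3) in limma with Benjamini-Hochberg adjustment.

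Limma called 410 genes in CR70 against CD, 134 higher and 276 lower, and 57 and 108 of them changed at least 2-fold. Groups did not overlap in 25.9% of genes, against 10% by chance. Of the genes called higher, 122 were also called higher in CR85, and of those called lower, 264 were also called lower in CR85. Independent lists of these sizes would share 4.42 and 15.96 genes. In 50 simulations of unchanged groups with simulated controls in common, 0 genes were shared on average. Unchanged groups give few or no calls after adjustment, so that 0 is no baseline for shared controls. The 3 controls were too few to divide, so part of the excess may come from the shared control arrays. The count was 17, 217 and 87 without CD replicates 1, 2 and 3 and 107, 82 and 129 without CR70 replicates 1, 2 and 3. It was 9 without the 4 arrays with testis transcripts, which leaves 1 array in CR70, assumed to vary like the other groups, and the other settings gave 11 to 1140.

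Energy metabolism lists were also called in CR70. De novo lipogenesis had 4 of 19 up (13 when adjusted over the list alone), Acacb, Aacs (1.41 ± 0.25), Mlxipl and Tkt. Acly differed by 1.13 ± 0.33 (adjusted p = 0.107). Further counts of genes that rose were 8 of 22 for the tricarboxylic acid cycle (19 over the list alone), 4 of 68 for oxidative phosphorylation (44 over the list alone), 2 of 21 for beta oxidation, Acot2 and Echs1 (13 over the list alone), and 2 of 17 for glycolysis, Pfkm and Ldhb (8 over the list alone). The adjusted p values of these 5 lists in camera were 1.37e-10, 1.08e-16, 5.89e-22, 7.48e-10 and 0.000667, and with an estimated correlation the adjusted p values were 0.183, 0.122, 0.154, 0.154 and 0.197. Without Pigq, glycolysis had 2 of 16 up (8 over the list alone), at adjusted p = 0.00133 and adjusted p = 0.213 with an estimated correlation. The clock list had 6 of 17 up and 2 down (9 and 3 over the list alone; adjusted p = 1.08e-05, adjusted p = 0.122 with an estimated correlation), with Dbp at 1.19 ± 0.23 and Nr1d2 at 1.12 ± 0.14. Matrix genes had 14 of 31 down (28 over the list alone), such as Col6a1 (-1.44 ± 0.26) and Col5a2 (-1.31 ± 0.14), macrophage genes 10 of 29 (21 over the list alone), such as Gpnmb (-1.42 ± 0.30) and Ccl6 (-1.40 ± 0.23), and markers of fat mass expansion 5 of 9 (6 over the list alone), such as Bmp3 (-1.81 ± 0.25) and Npr3 (-1.31 ± 0.29). These 3 lists had adjusted p values of 3.65e-24, 1.36e-17 and 6.19e-06, and adjusted p = 0.122 with an estimated correlation for each. Without Loxl3, matrix had 14 of 30 down (27 over the list alone), at adjusted p = 5.65e-24.

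Smaller shifts in CR70 included cholesterol synthesis (adjusted p = 0.00442), glucocorticoid-responsive genes (adjusted p = 0.0268), with Hsd11b1 at 1.08 ± 0.19 and Fkbp5 at 0.81 ± 0.14, and the NRF2 list (adjusted p = 4.62e-05), with Gsta4 at 1.25 ± 0.16. With an estimated correlation their adjusted p values were 0.435, 0.226 and 0.123. Lists that fell in camera were the unfolded protein response, B lymphocytes, T and NK lymphocytes with Thy1 (-0.84 ± 0.16), interferon response, adipose progenitors, endothelial cells, skeletal muscle with Acta1 (-2.00 ± 0.43), cell cycle and ribosomal proteins, at adjusted p values from 0.00200 to 0.0474 and from 0.226 to 0.435 with an estimated correlation. Of these, skeletal muscle rested on CD replicate 2, whose list mean was 6.65 against 5.74 and 5.95 in the other controls and 5.56 to 5.72 in CR70. Without that array its adjusted p was 0.256, and that of the glucocorticoid list 0.0765. Without CD replicate 1, adjusted p values were 0.0563 for B lymphocytes, 0.339 for cell cycle and 0.154 for ribosomal proteins. Without CD replicate 3 they were 0.0635 for glucocorticoid-responsive genes and 0.0795 for ribosomal proteins. Without CR70 replicate 1 they were 0.0780 for cholesterol synthesis and 0.208 for ribosomal proteins. Leaving out CR70 replicate 2 gave 0.176 for endothelial cells, 0.237 for cell cycle and 0.167 for ribosomal proteins. Leaving out CR70 replicate 3 gave 0.0879 for interferon response. The cell cycle mean was 5.96 and 5.97 in CR70 replicates 1 and 3, which held testis transcripts, and 5.75 in replicate 2, which did not. Cell cycle was at 0.0524 without CR85 replicate 2, and cell cycle and ribosomal proteins were at 0.0590 and 0.0523 without CR55 replicate 2 and at 0.0525 each without CR55 replicate 3. The testis list was higher (median 1.47, adjusted p = 0.00357, adjusted p = 0.435 with an estimated correlation, adjusted p = 0.156 without CR70 replicate 3), with 2 of the 3 CR70 arrays above all controls. Adipoq (-0.04 ± 0.11), Pck1 (-0.17 ± 0.38), Ucp1 (-0.13 ± 0.14) and Fasn (0.43 ± 0.13) did not pass, with adjusted p values of 0.917, 0.888, 0.712 and 0.116. In Cidea, Ppargc1a (1.25 ± 0.26) and Otop1 (-0.88 ± 0.18) the thermogenic list had 2 of 15 up and 1 down and was not called (adjusted p = 0.0569). It was called without CD replicate 2 (adjusted p = 0.0409), CD replicate 3 (0.0346), CR70 replicate 2 (0.0301) or CR55 replicate 1 (0.0437). The mesothelial list (adjusted p = 0.0569) was called as lower without CD replicate 3 (0.000752) or CR70 replicate 2 (0.000917). Lists whose median and mean differed in sign were lipolysis (0.11 and -0.02), insulin signalling (0.05 and -0.01) and adipocyte identity (-0.08 and 0.02), none of them called. In all, camera called 22 lists, 10 up and 12 down, fry called 12, and camera with an estimated correlation called 0, with 8 at an unadjusted p under 0.05.

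CR55, the strongest restriction by its label, lay closest to the control diet. Lep differed by -0.92 ± 0.46, Mest by -1.07 ± 0.49, Sfrp5 by -0.85 ± 0.49, Nnat by 0.04 ± 0.52 and Acsm3 by 1.13 ± 0.55, and none of these passed (adjusted p from 0.851 to 0.998). The genes with the smallest p were Inmt (1.36 ± 0.20), Oscp1 (1.15 ± 0.18) and Fdft1, the squalene synthase gene (1.08 ± 0.18), on the higher side and Rnase2a (-2.15 ± 0.34), Rab27b (-0.84 ± 0.14) and Sh3pxd2b (-0.58 ± 0.10) on the lower side. Limma with Benjamini-Hochberg adjustment called 0 of 19938 genes, with a smallest adjusted p of 0.238, 1168 genes at an unadjusted p under 0.05 where chance gives 996.9, and 1 call without moderation of the variance. The count was also 0 without the 4 arrays with testis transcripts, with a smallest adjusted p of 0.0900. The 3 arrays differed among themselves: Sfrp5 was 6.24 in replicate 1 and 8.35 and 8.68 in replicates 2 and 3, and Lep was 9.72, 11.1 and 11.3. Groups did not overlap in 13.2% of genes, against 10% by chance.

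Calls of lists in CR55 depended on the test. With an estimated correlation 0 lists were called (smallest adjusted p = 0.238, 6 lists at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.104). Camera at the preset correlation called 13 lists, 8 up and 5 down, but 5 of the 10 splits of these 6 arrays, the real one included, called as many, and a mixed split called 19. Those higher were the tricarboxylic acid cycle (median 0.28, adjusted p = 1.13e-11), oxidative phosphorylation (0.20, adjusted p = 2.76e-13), beta oxidation (0.25, adjusted p = 1.54e-08), the clock (0.42, adjusted p = 1.39e-06), de novo lipogenesis (0.26, adjusted p = 0.000555), NRF2 (0.17, adjusted p = 0.000662), glycolysis (0.15, adjusted p = 0.0154) and testis germ cells (1.15, adjusted p = 0.00615), the last with 1 of 3 arrays above all controls. Those lower were matrix (-0.52, adjusted p = 2.84e-16), macrophages (-0.32, adjusted p = 1.54e-08), the unfolded protein response (-0.11, adjusted p = 0.00202), fat mass expansion (-0.37, adjusted p = 0.00297) and ribosomal proteins (-0.08, adjusted p = 0.0302). Glycolysis was at adjusted p = 0.0193 without Pigq and matrix at adjusted p = 3.25e-16 without Loxl3. Lists not called without CR55 replicate 1 were de novo lipogenesis (adjusted p = 0.383), glycolysis (0.207), fat mass expansion (0.135) and ribosomal proteins (0.531). Without CD replicate 1, glycolysis (0.203) and ribosomal proteins (0.171) were not called, nor were ribosomal proteins without CD replicate 3 (0.0523) and testis germ cells without CR55 replicate 2 (0.398). Adjustment over the list alone is not corrected across the 31 lists, and 0 of 19938 genes passed when adjusted over all genes. Within their lists, limma called 12 of 31 matrix genes lower, with Postn at -0.73 ± 0.17 and Col6a1 at -0.90 ± 0.26. It called 6 clock genes higher and 1 lower, with Ciart at 1.61 ± 0.35 and Nr1d2 at 0.75 ± 0.14. Fatty acid uptake and triglyceride synthesis had 3 genes higher and 1 lower, and NRF2 had 2 higher, with Gsta4 at 0.87 ± 0.16. Values of Acly (0.32 ± 0.33), Fasn (0.14 ± 0.13), Pck1 (0.29 ± 0.38), Adipoq (0.13 ± 0.11) and Ucp1 (0.03 ± 0.14) did not pass either. Median, mean and test differed in sign for adipokines (median 0.03, mean -0.17), glucocorticoid-responsive genes (-0.01 and 0.06), interferon response (mean 0.03, median just below 0) and insulin signalling (-0.02 and -0.02, tested as up), and none of these lists was called. Further lists were called only with an array left out. Without CD replicate 1 these were glucocorticoid-responsive genes (adjusted p = 0.0184) and skeletal muscle (0.00359). Without CD replicate 2 they were fatty acid uptake and triglyceride synthesis (0.0178), B lymphocytes (0.0125) and thermogenic adipocytes (0.0491). Without CD replicate 3 they were B lymphocytes and mesothelial cells (0.000203 each), thermogenic adipocytes (0.0309) and skeletal muscle (0.0404). Leaving out CR55 replicate 1 added the glucocorticoid list (0.0362) and cholesterol synthesis (0.0322, lower). Leaving out CR55 replicate 2 added cell cycle (0.000584), B lymphocytes (0.0251) and fatty acid uptake (0.0487), and CR55 replicate 3 skeletal muscle (0.00559) and fatty acid uptake (0.0246). The cell cycle mean was 6.31 in CR55 replicate 2, an array with testis transcripts, against 5.79 and 5.86 in replicates 1 and 3. Whether testis RNA raised it was not tested. Fatty acid uptake was called without CR85 replicate 1 (0.0365) and B lymphocytes without CR85 replicate 2 (0.0494).

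The direct comparison of CR55 with CR85, which does not use the control means, separated the restrictions labelled as strongest and mildest. On the log2 scale Nnat was higher in CR55 by 5.43 ± 0.52, Mest by 4.56 ± 0.49 and Sncg by 4.0 ± 0.32. The CR85 means of Nnat, Mest and Slc6a13 (5.55, 6.30 and 6.29) lay near the column median of 6.12, and without a background level the size of their changes is uncertain. Slc6a13 was higher by 2.93 ± 0.50 and Npr3 6.12-fold, while Elovl3 (-3.14 ± 0.59), Lrtm1 (-2.81 ± 0.39), Mpzl2 (-2.43 ± 0.36), Cyp2f2 (-2.26 ± 0.31) and Cyp51 (-2.22 ± 0.42) were lower. Limma with Benjamini-Hochberg adjustment called 581 genes, 433 higher and 148 lower in CR55. Markers of fat mass expansion had 6 of 9 higher and 1 lower (6 and 1 when adjusted over the list alone), macrophage genes 9 of 29 higher (20 over the list alone) and matrix genes 10 of 31 higher (14 over the list alone; 10 of 30 and 14 without Loxl3). Camera called 17 lists and fry 11, and with an estimated correlation 0 were called (smallest adjusted p = 0.285, 3 lists at an unadjusted p under 0.05). Median, mean and test differed in sign for adipokines (median -0.04, mean 0.35), mesothelial cells (0.01 and -0.01), epididymis (0.01 and -0.02) and red blood cells (0.05 and 0.01, tested as down), none of them called. The count of genes was 195 and 336 without CR85 replicates 1 and 3 and 156 and 113 without CR55 replicates 2 and 3. It was 157 without the 4 arrays with testis transcripts and 22 with only the 6 arrays compared.

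Neighbouring steps differed less. In CR70 against CR85 limma called 7 genes, all higher in CR70, among them Sncg (2.50 ± 0.32), Zfp772 (1.75 ± 0.21), Itih5 (1.13 ± 0.09), the chemokine gene Cxcl9 (1.11 ± 0.15) and Slc27a6 (0.98 ± 0.14), at adjusted p values from 0.00192 to 0.0439. That count was 1 to 4 without any of CD replicates 1, 2 and 3 (2, 1 and 1), CR85 replicates 1, 2 and 3 (1, 2 and 1), CR70 replicates 1, 2 and 3 (4, 4 and 1) or CR55 replicates 2 and 3 (2 and 1), and 0 without the 4 arrays with testis transcripts or with only the 6 arrays compared. In CR55 against CR70 limma called 0 genes, with 1431 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0652, 9 without CR55 replicate 1, 1 without CD replicate 3 and 1 each with trended robust variance and with the genes of lowest mean value left out, and 0 without the 4 arrays. Camera called 12 lists in CR70 against CR85 and 16 in CR55 against CR70, and with an estimated correlation 0 in each (smallest adjusted p values 0.521 and 0.372, with 2 lists in each at an unadjusted p under 0.05).

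**Figure D4:**
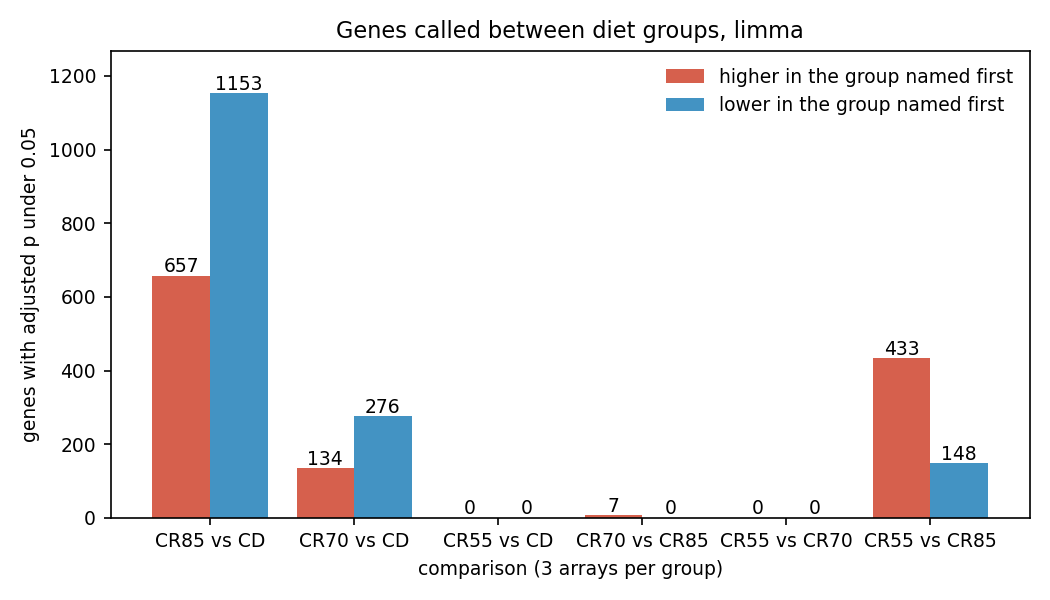
Number of genes called by limma at an adjusted p under 0.05 in each of 6 comparisons, split into genes higher (red) and lower (blue) in the group named first, with 3 arrays per group. CR85 against CD has 657 and 1153 genes, CR70 against CD 134 and 276, and CR55 against CD 0 and 0.

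Across the 4 diets the response did not follow a straight line in the labelled restriction. Mest averaged 11.9 ± 0.23 (SD, n = 3) in CD, 6.30 ± 0.51 in CR85, 8.76 ± 0.73 in CR70 and 10.9 ± 1.03 in CR55. Acsm3 averaged 6.45 ± 0.59, 9.76 ± 0.34, 9.21 ± 0.67 and 7.58 ± 1.27 in that order. For the linear trend limma called 0 genes, with 718 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. In that linear fit, departures of the diets from the line count as error, which makes the test of the slope less sensitive. The moderated F tests called 1335 genes for a departure from the line and 961 for any difference among the diets. Of these 961 genes, 870 lay farthest from CD in CR85, 76 in CR70 and 15 in CR55, and the means of 762 ran in the order CD, CR55, CR70, CR85 against 7 in the labelled order, where chance gives 8.33% for each order. Camera on the trend called 11 lists, 7 up and 4 down, with the testis list among those higher (adjusted p = 0.000128, adjusted p = 0.306 without CR55 replicate 2), and with an estimated correlation 0 (smallest adjusted p = 0.736, 1 list at an unadjusted p under 0.05), and fry called 0. Of the 11 lists, 4 were also called without CD replicate 1, where adjusted p values were 0.557 for oxidative phosphorylation, 0.192 for matrix, 0.178 for the tricarboxylic acid cycle, 0.106 for beta oxidation, 0.729 for macrophages (then tested as up), 0.407 for NRF2 and 0.0730 for the unfolded protein response. The last 3 of these were at 0.0691, 0.187 and 0.208 without CD replicate 2 and at 0.128, 0.205 and 0.116 without CD replicate 3. NRF2 was at 0.0632, 0.0510 and 0.0583 without CR70 replicates 1, 2 and 3, and the unfolded protein response at 0.0532 without CR55 replicate 3. Without CR55 replicate 1, fatty acid uptake and triglyceride synthesis was at 0.158 and ribosomal proteins at 0.0975. Lists called on the trend only without CD replicate 1 or another array were T and NK lymphocytes (0.0367), interferon response (0.0123), adipocyte identity (0.0421, and 0.0166 and 0.0368 without CD replicates 2 and 3) and cholesterol synthesis (0.00618, and 0.0113 without CD replicate 3). Skeletal muscle was so called without CD replicate 1 (0.0396) or CR55 replicate 3 (0.000906), and mesothelial cells without CD replicate 3 (0.00600), CR85 replicate 1 (0.0304) or CR70 replicate 2 (0.0287). De novo lipogenesis was called without CR55 replicate 2 (0.0209) or 3 (0.000426), glycolysis without CR55 replicate 3 (0.0486) and cell cycle without CR55 replicate 2 (0.0473).

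The departure count was 661 without CD replicate 1, 856 without CD replicate 3 and 676 without CR85 replicate 1, and 711 without the 4 arrays with testis transcripts. The count of any difference was 365, 557 and 465 without CD replicates 1, 2 and 3, 438 and 636 without CR85 replicates 1 and 3, and 391 without those 4 arrays.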

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

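The tests of other sample splits were set before the results were seen, while the tests behind both patterns weighed here, the group order and the testis transcripts, were chosen only after the results they concern had been seen.

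The direct comparison of CR55 with CR85, a difference between groups, called 581 genes, and that of CR70 with CR85 called 7. Data outside the tests carried signal too: in CR85 against CD limma called 216 of the probe sets with no listed gene (3.97%), 65 higher and 151 lower, and 78 of those with several genes (4.81%), 17 higher and 61 lower, against 8.16% of those with 1 gene.

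The group labelled CR85 lay farthest from the control diet and the group labelled CR55 nearest to it. Testis RNA in 4 arrays is argued against as the whole cause, because 157 genes were still called between CR55 and CR85 without those arrays. Over all genes, the median SD of the CR55 arrays was 1.05 times the median of the other groups. That value cannot speak for the responding genes alone. The mean of the fat mass expansion list was 8.04, 8.81 and 9.17 in CR55 replicates 1, 2 and 3, against 9.01 to 9.28 in the controls. A larger scatter of CR55 in such genes is left open. Exchanged labels of CR85 and CR55 and a weaker response at the strongest restriction would both give the order CD, CR55, CR70, CR85, in which the means of 762 of 961 genes ran, and cannot be told apart because no value of these arrays separates them. A trend over that order called 2622 genes, against at most 585 for any of the 11 other orders and 0 for the labelled order, but the order had been seen in the means, so this count restates the pattern and supports neither. The labels are kept as given, and every statement about the strength of restriction depends on them.

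Testis germ cell transcripts stood out in CR85 replicate 2, CR70 replicates 1 and 3 and CR55 replicate 2. The 4 arrays were picked on the mean of all 12 list members, and the first 6 members alone picked the same 4. Of the other 6, 5 were higher in all 4 arrays than in all 8 others, as RNA from testis tissue would give. Such tissue may have come along with the depot. Because those 6 also counted in the first pick, this is not a separate check. Ldhc, one of those 6, averaged 8.59 in the 4 arrays. Prm2, one of the first 6, averaged 10.3, and both genes were chosen after their values were seen. Of the 12 list members, 4 lay above the column median in the control arrays. A list of 10 meiotic germ cell genes, written after the data were seen, shares no member with the testis list. It averaged 4.72 to 5.86 in the 4 arrays and at most 4.22 in the other 8, all under the column median of 6.12. Induction of germ cell genes in all samples of a restricted diet is argued against, since 0 restricted groups had all 3 arrays above all controls in the testis list. Epididymis as the source of these transcripts is argued against by a difference of -0.0423 in its list, against 2.74 for the testis list. Genes of the efferent ducts, which join testis and epididymis, averaged 1.67 above the other 11 arrays in CR85 replicate 2 and 0.72 above in CR70 replicate 3. Leydig cell genes averaged 6.39 in CR70 replicate 3 but 4.73 in CR85 replicate 2, within the range of the 8 arrays without testis transcripts. Which tissues came along, and whether they were the same in the 4 arrays, is left open.

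For comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. The genes called in the real split and the highest count of the other splits were 1810 and 0 for CR85 against CD, 410 and 0 for CR70 against CD, 0 and 1 for CR55 against CD, 7 and 0 for CR70 against CR85, 0 and 2 for CR55 against CR70, and 581 and 0 for CR55 against CR85. The real split was alone in reaching its count, 1 of 10, in the comparisons with calls, and all 10 splits reached the count of 0, as any split must. For lists, the values were 20 and 15 in CR85, 22 and 16 in CR70 and 13 and 19 in CR55, where 5 of 10 splits called as many. Of 100 splits of all 12 arrays, 1 (the real one) called as many genes for the departure from the line (1335, highest other 940). For any difference 1 did so, again the real one (961, highest other 874). Chance is therefore unlikely there, but 100 splits cannot exclude it. For the trend in genes all 100 reached the real count of 0 (highest other 148), as any split must, so this says nothing about chance. For the trend in lists 39 called as many as the real 11 (highest other 20), so chance cannot be excluded.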

How the results depend on the processing

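The fits without the 4 arrays with testis transcripts and with the testis list mean as covariate, and the lists without Pigq and Loxl3, were chosen after seeing the data, and the other alternatives were planned.

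Counts stayed within 1.5 times the reported value under 21 of 26 alternatives for CR85 against CD, 13 of 26 for CR70 against CD, 25 of 26 for CR55 against CD, 6 of 26 for CR70 against CR85, 22 of 26 for CR55 against CR70, 18 of 26 for CR55 against CR85, 15 of 24 for any difference, 18 of 24 for the departure and 24 of 24 for the trend. Lists did so under 23, 22, 22 and 22 of 24 for CR85, CR70, CR55 and the trend. The cause was not tested unless given here.

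With the genes of lowest mean value left out, which tests fewer genes, CR70 against CD gave 778 genes, CR70 against CR85 18 and CR55 against CR70 1. With trended robust variance these were 725, 17 and 1. Without moderation, CR70 against CD gave 166, CR55 against CD 1, CR70 against CR85 4, CR55 against CR85 373 and any difference 625. Array weights gave 2903 for CR85 against CD, 1140 for CR70 against CD, 27 for CR70 against CR85, 2005 for the departure and 1660 for any difference. At an adjusted p under 0.01, a stricter threshold, CR85 against CD gave 770, CR70 against CD 11, CR70 against CR85 1, CR55 against CR85 102, the departure 442 and any difference 275. With only the 6 arrays compared, and so fewer arrays, CR85 against CD gave 1130, CR70 against CR85 0 and CR55 against CR85 22.

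Without the 4 arrays with testis transcripts, which leaves CR70 with 1 array assumed to vary like the other groups, CR70 against CD gave 9 genes (6 shared with the 410), CR70 against CR85 0, CR55 against CR85 157 (119 shared), the departure 711 and any difference 391. With the testis list mean as covariate CR70 against CR85 gave 3. With the replicate block CR70 against CD gave 263 and CR70 against CR85 1. Of 18 pairs with a shared replicate number 6 had deviations correlated above 0.1 across genes (r from -0.596 to 0.481), among them all 3 of CR85 with CR55 (0.320, 0.481 and 0.284), and 3 of 12 arrays were closest to one of their own number. In CR85 and CR55 alike, replicate 2 was the array with testis transcripts, so testis RNA alone could give these 3 positive values. CR70 replicate 2, without such transcripts, ran against both (r = -0.472 and -0.596). The correlations therefore cannot tell whether the numbers pair CR85 with CR55. In that comparison the block gave 462 genes, 411 of them shared with the 581. Camera with an estimated correlation called 0 lists in CR85, 0 in CR70, 0 in CR55 and 0 for the trend, and fry called 12 in CR70, 0 in CR55 and 0 for the trend. Without Pigq and Loxl3 camera called 20, 22, 13 and 11.

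Leaving out 1 array at a time gave 831 to 2117 genes for CR85 against CD, 17 to 487 for CR70 against CD, 0 to 0 for CR55 against CD, 1 to 7 for CR70 against CR85, 0 to 9 for CR55 against CR70, 113 to 817 for CR55 against CR85, 0 to 0 for the trend, 661 to 1525 for the departure and 365 to 963 for any difference. Lists ranged from 17 to 21, 19 to 23, 11 to 16 and 9 to 13 for CR85, CR70, CR55 and the trend.

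Among 354 values of named genes, quantile normalization left 354 on their side of the threshold, leaving out CD replicate 1 took 96 below it and leaving out the 4 arrays 92. The columns already shared their quartiles before quantile normalization, so that setting could change little. No called value among the 354 reversed. Without the 4 arrays, uncalled values that reversed were Adipoq in CR70 against CD (0.022) and, in CR55 against CD, Ucp1 (-0.050), Pgk2 (-0.0024), Akap4 (-0.040), Tnp2 (-0.12), Gapdhs (-0.17) and Hemgn (-0.088). Over single arrays left out, Adipoq in CR70 against CD ran from -0.077 to 0.019, and in CR55 against CD Ucp1 ran from -0.050 to 0.14, Acly from -0.014 to 0.70, Pgk2 from -0.0024 to 1.99, Akap4 from -0.040 to 2.10, Tnp2 from -0.12 to 1.71, Gapdhs from -0.17 to 1.91, Hemgn from -0.088 to 0.41 and Slc4a1 from -0.13 to 0.25. The alternative for a linear scale was not run, since the values are on a log2 scale, and signal over background was not used here.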

Other observations

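The lists in this part were written after the data had been seen, so all tests on them were chosen after seeing results.

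Of 17 measured genes that break down branched-chain amino acids, 10 rose in CR85 and 0 fell (median 0.53), among them Bcat2 (1.37 ± 0.23), Bckdha (1.09 ± 0.18), Ivd (1.02 ± 0.14) and Pccb (0.82 ± 0.11). In CR70 3 rose (median 0.57). In CR55 limma called 0 (median 0.34, smallest adjusted p = 0.730, 8 at an unadjusted p under 0.05). Camera at the preset correlation gave adjusted p values of 1.21e-11, 1.35e-10 and 8.18e-11, and with an estimated correlation adjusted p values of 0.150, 0.162 and 0.277.

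Of 19 peroxisome genes, Crat (0.99 ± 0.17), Ehhadh (0.73 ± 0.14), Abcd3 and Phyh rose in CR85 (median 0.33, adjusted p = 0.000314, adjusted p = 0.312 with an estimated correlation). In CR70 1 rose (median 0.37, adjusted p = 4.40e-06, adjusted p = 0.162 with an estimated correlation). In CR55 limma called 0 (2 at an unadjusted p under 0.05; median 0.15, adjusted p = 0.000142, adjusted p = 0.277 with an estimated correlation). Of 16 measured imprinted growth genes, Mest, Nnat, Peg3 (-1.44 ± 0.31), Plagl1 (-1.39 ± 0.16), Ndn (-1.18 ± 0.23) and Sgce (-0.79 ± 0.18) fell in CR85, while Igf2 (0.08 ± 0.20) and Dlk1 (0.36 ± 0.20) did not pass (median -0.47, adjusted p = 0.000314, adjusted p = 0.150 with an estimated correlation). In CR70 4 fell (median -0.22, adjusted p = 0.000339, adjusted p = 0.162 with an estimated correlation). In CR55 limma called 0 (2 at an unadjusted p under 0.05; median -0.07), and the list was not called (adjusted p = 0.129).

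A list of efferent duct epithelium genes averaged 7.67 in CR85 replicate 2, 1.67 above the mean of the other 11 arrays, 6.80 in CR70 replicate 3 and 5.73 to 6.21 in the other 10. Leydig cell genes averaged 6.39 in CR70 replicate 3, 5.79 in CR55 replicate 2, 5.45 in CR70 replicate 1 and 4.73 in CR85 replicate 2, against 4.49 to 4.91 in the other 8.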
